A study of Mus musculus with 18 samples.

How the data were processed

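Total RNA of F9 cells was extracted and labelled with biotin, per the labels' protocols, and measured on Affymetrix whole-transcript arrays. The deposited table held log2 levels per probe set for 18 arrays, made by the authors with Affymetrix Expression Console 1.1 and RMA, per the submitters' processing notes. Which arrays were normalized together, scan dates and detection calls are not given in the sources used here. The values, between 2.05 and 14.36, were taken as deposited, with no further scaling.

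A platform annotation paired probe sets with genes: 21789 probe sets had 1 gene symbol, 1621 had several and 12146 were not listed, and 21698 were matched to a gene table by their Entrez number. Probe sets with several or no symbols were not named. A gene was the probe set with 1 symbol, and for the 999 genes with several probe sets the one with the highest mean over the 18 arrays; this left 19938 genes, with no filter on dim ones. Of 501 list members 462 were measured.

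Samples were grouped by agent and time from the labels. With 1 array for each retinoid and time, a fit of single times would rest on 1 residual degree of freedom, from the vehicle pair, so single times are given as values and a linear model in limma 3.58.1 (R 4.3.3) was fitted to all 18 arrays with 9 group means (vehicle, and each retinoid early and late) and common steps from 2 to 6 h and from 24 to 48 h. It left 7 residual degrees of freedom and a prior of 4.55 from eBayes. The spread came from the vehicle pair and from departures of the retinoids from the common steps. The comparison of ATRA and BMS961 with BMS753 and BMS641 used the 16 retinoid arrays, with time as a block and the class within early and within late (10 residual degrees of freedom, prior 4.30). Calls were at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Intervals of 95% came from the same fit. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.

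Gene lists, comparisons, the first set of other settings and the rule for named genes were fixed before the data were examined. The 24 lists, from textbook knowledge, were retinoid receptors and retinoid metabolism, early retinoid target genes, Hox clusters A and B, Hox clusters C and D, pluripotency, primitive and parietal endoderm, visceral endoderm, basement membrane and matrix assembly, neural, mesoderm and primitive streak, trophoblast, fibroblast, DNA replication and S phase, mitosis, CDK inhibitors and growth arrest, MYC, cyclin D and growth regulators, p53 targets and apoptosis, NODAL, BMP and TGF-beta signalling, WNT signalling, cholesterol synthesis, hypoxia and glycolysis, stress and immediate early response, interferon response, and ribosomal proteins. They were tested with camera at a preset correlation of 0.01, adjusted over 120 tests (24 lists in 5 comparisons), and again with an estimated correlation. Named genes were the 10 largest called rises and 10 largest falls per retinoid late against vehicle whose late arrays both lay on the same side of both vehicle arrays, the 5 and 5 largest early by the same rule, the 10 and 10 largest of the late class comparison with every array of one class above the other at the same time, and the 5 and 5 largest per pair of retinoids with the same sign at 24 h and 48 h. List members could be named besides.

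Both fits were tested on simulated data with 200 changed genes among 19938. For ATRA late against vehicle, 86.6%, 98.5% and 100% of the genes changed 2-, 4- and 8-fold were recovered, with 10 false calls; for the late class comparison 92.5%, 100% and 100%, with 12. A simulated pluripotency list lowered 2-fold was called, with 2 other calls among the 120 list tests. Unchanged groups were simulated 50 times against shared vehicle arrays for the correlation of changes. The other settings fixed then were quantile normalization, arrays centred on their median, genes above the median mean level only, the mean of a gene's probe sets, eBayes with trend and robust, a minimum of 2-fold, no common steps, late arrays and vehicle only, 17 group means, each ligand within phase plus time, leaving out each array or retinoid, and for single times 1.5-fold, 3-fold and the mean of the vehicle arrays. The array set as a block, the vehicle array of the same set, and lists without ATRA (class comparison) or without single vehicle arrays were added after seeing the data. Nothing was left out of the 18 arrays; the probe sets without a listed gene were used for the array sets and for the closing part.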

Results

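F9 cells are a mouse embryonal carcinoma line that differentiates when given retinoic acid. The cells received ethanol vehicle or 1 of 4 retinoids, and their total RNA was measured on Affymetrix whole-transcript arrays. All-trans retinoic acid (ATRA) activates every retinoic acid receptor (RAR); per the labels, BMS961 is specific for RARγ, BMS753 for RARα and BMS641 for RARβ. ATRA, BMS753 and BMS641 were used at 1 µM and BMS961 at 0.1 µM, so comparisons with BMS961 were not at a matched dose. The 18 arrays were 2 of vehicle at 48 h and 1 of each retinoid at 2, 6, 24 and 48 h (n = 1 for each retinoid and time). The labels do not say whether the vehicle arrays came from separate cultures, so the spread of that pair may be technical. The p-values of the fit to all 18 arrays rest on that pair and on departures of the retinoids from the common steps. Such departures can hold real differences in time course. These p-values therefore do not measure the spread between repeated cultures.

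The log2 levels of the probe sets lay between 2.05 and 14.36, and the medians of all probe sets per array between 5.31 and 5.47; the number of arrays limits the precision. The comparisons used 19938 genes. The 24 h and 48 h arrays of a retinoid were averaged as late, and its 2 h and 6 h arrays as early; these are different times, not replicates. Changes are given on the log2 scale ± SE of the limma fit. The vehicle arrays themselves differed by a median of 0.23 (absolute log2 difference), with 311 genes at least 2-fold higher and 354 at least 2-fold lower in vehicle replicate 1 than in replicate 2. Over the 12146 probe sets without a listed gene, the deviations of the arrays from the mean over all 18 had a mean correlation of 0.283 within a set of 5 arrays (vehicle replicate 1 and the 4 ATRA arrays), 0.005 within the other 13 arrays and -0.185 across both sets. Vehicle replicate 1 had a mean of 0.322 with the ATRA arrays and -0.189 with the BMS arrays, and vehicle replicate 2 -0.262 and 0.037. By the correlation of levels all 4 ATRA arrays, but also 4 of the 12 BMS arrays, were closer to vehicle replicate 1 than to replicate 2. These are correlations across probe sets, which are not independent replicates. The labels name no batch, and the sets were grouped on the values. If the sets differ technically, every comparison of ATRA with a BMS compound coincides with that difference, so values with the array set as a block, an alternative chosen after seeing the data, are given beside the results against vehicle and between ATRA and a BMS compound, and values without ATRA beside the late class comparison. Each set held 1 vehicle array, so the block compared ATRA with vehicle replicate 1 alone and the BMS compounds with vehicle replicate 2 alone. Blocked results against vehicle thus rest on 1 control array. They repeat the fits without the other vehicle array and are no separate check. Between ATRA and a BMS compound the block subtracts the difference of the 2 vehicle arrays.

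The late ATRA arrays show which genes differed from vehicle with a pan-RAR ligand. Both vehicle arrays were at 48 h, so the 24 h array of each retinoid also differed from them in time in culture. Cyp26a1, the enzyme that degrades retinoic acid, rose most, by 6.54 ± 0.31 (92.9-fold, adjusted p = 1.53e-06). The retinoic acid receptor gene Rarb rose by 3.71 ± 0.35 (13.1-fold) and Dhrs3, which reduces retinaldehyde, by 3.46 ± 0.42. The homeobox genes Hoxa5 and Hoxb2 rose by 4.56 ± 0.18 (23.6-fold, adjusted p = 3.37e-07) and 3.75 ± 0.33 (13.4-fold). Gata6, a transcription factor of primitive endoderm, rose 10.2-fold. Otx2, a homeobox gene of the epiblast, fell by 8.76-fold (-3.13 ± 0.38, adjusted p = 0.00173). The remaining named rises were Stra8 (3.80), which is needed for entry into meiosis, the retinoic acid binding protein gene Crabp2 (3.66), Calcoco2 (3.50) and the water and glycerol channel Aqp3 (3.37). The remaining named falls were Enox1 (-2.41), Platr8 (-2.39), Pcolce2 (-2.23), Dnmt3l (-2.22), Septin1 (-2.20), Tcea3 (-2.14), Pdzd4 (-1.99), Hmces (-1.98) and the guidance cue gene Ntn1 (-1.97). In all, limma called 940 genes in ATRA late against vehicle, 660 higher and 280 lower, and 421 of them changed at least 2-fold. The array medians over the 19938 genes lay 0.14 higher on the late ATRA arrays than on the vehicle arrays, while the median change over genes was -0.02. With arrays centred on their median the calls were 394 higher and 370 lower, and after quantile normalization 520 and 436. A block for the array set left 175 genes called (108 higher, 67 lower), among them 13 of the 20 named genes, and the counts without vehicle replicate 1, vehicle replicate 2, the 24 h array and the 48 h array were 3594, 175, 1655 and 148. The 7 named genes that no longer passed with the block were Stra8 (2.16), Crabp2 (3.86), Calcoco2 (1.74), Aqp3 (1.91), Gata6 (2.83), Dnmt3l (-1.49) and Septin1 (-2.22). Their signs could not turn, because genes were named only if both late arrays lay on the same side of both vehicle arrays.

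**Figure D1:**
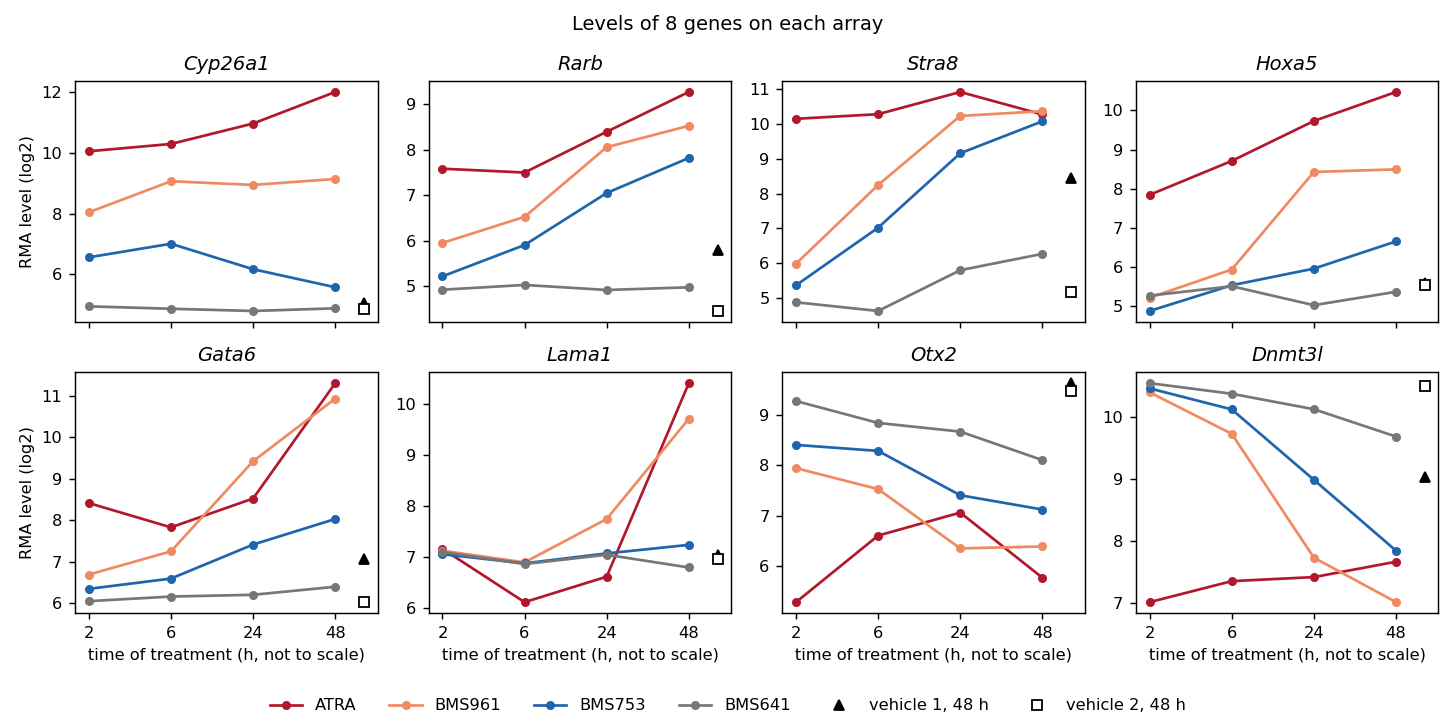
Log2 RMA level (vertical axis) of 8 genes on each of the 18 arrays against the time of treatment in hours (horizontal axis, not to scale), with 1 line per retinoid and separate markers for the 2 vehicle arrays at 48 h; each point is 1 array. Cyp26a1 reached 12.01 with ATRA and 9.14 with BMS961 at 48 h against 5.05 and 4.85 in vehicle, while Stra8 lay at 8.44 and 5.17 on the vehicle arrays.

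The gene lists, written before the data were examined, showed where the ATRA calls fell. Pairs of counts adjusted over the list alone give rises (or higher genes) first, then falls (or lower genes). Of the 21 measured genes of retinoid receptors and retinoid metabolism, 8 rose and 0 fell (9 and 0 adjusted over the list alone), including Stra6 (2.54 ± 0.27), which takes up retinol, and Rdh10 (0.82 ± 0.18), which oxidises it. The retinoid metabolism list had camera adjusted p = 1.11e-06, adjusted p = 0.0876 with an estimated correlation. Among 20 early retinoid target genes 11 rose, with Nrip1 at 2.20 ± 0.17, Foxa1 at 2.19 ± 0.28 and Meis2 at 2.10 ± 0.29, and 1 fell, Pdgfa at -0.86 ± 0.16 (12 and 1 adjusted over the list alone). The early target list had camera adjusted p = 1.11e-06, adjusted p = 0.0941 with an estimated correlation. In Hox clusters A and B 11 of 18 genes rose and 0 fell (13 and 0 adjusted over the list alone), with Hoxb5 at 2.80 ± 0.21 and Hoxb4 at 2.33 ± 0.17. The Hox A and B list had camera adjusted p = 6.33e-18, adjusted p = 0.12 with an estimated correlation. In Hox clusters C and D 0 of 18 genes rose over all genes tested by limma, and 5 and 0 adjusted over the list alone. The Hox C and D list had camera adjusted p = 0.0194, adjusted p = 0.369 with an estimated correlation. Of 26 pluripotency genes 0 rose and 11 fell (1 and 12 adjusted over the list alone). Among the falls were Tcl1 at -1.75 ± 0.17, Prdm14 at -1.50 ± 0.25, Zfp42 at -1.26 ± 0.22 and Sox2 at -0.64 ± 0.16. The pluripotency list had camera adjusted p = 2.34e-07, adjusted p = 0.201 with an estimated correlation. Pou5f1 and Nanog, core pluripotency factors, had values of -0.24 ± 0.11 and 0.16 ± 0.24 and did not pass the test. The array set as a block left 4 of the 8 called genes of retinoid metabolism past the threshold, 5 of 12 early targets, 8 of 11 Hox A and B genes and 6 of 11 pluripotency genes. Rdh10 (0.97, adjusted p = 0.0648) and Sox2 (-0.73, adjusted p = 0.133) did not pass with it.

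Of 23 genes of primitive and parietal endoderm, 7 rose with late ATRA and 1 fell (14 and 1 adjusted over the list alone). Gata4 rose by 2.03 ± 0.44, Sox7 by 1.59 ± 0.35 and the proteoglycan core gene Srgn by 3.16 ± 0.70, and the activin-binding Fst had a change of -1.68 ± 0.16. The primitive endoderm list had camera adjusted p = 1.54e-08, adjusted p = 0.343 with an estimated correlation. In the basement membrane and matrix assembly list 5 of 23 genes rose and 0 fell (11 and 0 adjusted over the list alone): Fbln1 (1.49 ± 0.24), the collagen chaperone Serpinh1 (1.00 ± 0.25), the collagen hydroxylases P4ha2 and Plod1, and Dag1. The basement membrane list had camera adjusted p = 2.94e-08, adjusted p = 0.35 with an estimated correlation. The visceral endoderm list had 0 of 19 genes called by limma over all genes, 0 and 0 adjusted over the list alone, and a median of 0.16. The visceral endoderm list had camera adjusted p = 0.0489, adjusted p = 0.464 with an estimated correlation. The median of the primitive and parietal endoderm list against vehicle replicate 1 was -0.12, -0.41, 0.04 and 2.02 at 2, 6, 24 and 48 h of ATRA, and that of vehicle replicate 1 against 2 was 0.45; for the basement membrane list the vehicle difference was 0.42. In the fit with the array set as a block, camera passed 10 lists in ATRA late, among them pluripotency (adjusted p = 8.4e-16), primitive and parietal endoderm (adjusted p = 6.43e-07) and basement membrane (adjusted p = 7.94e-06); with an estimated correlation 0 of the 24 lists passed in any of the 5 comparisons tested, against 16, 9, 11, 9 and 16 with the preset correlation. By single genes the block left 2 of the 8 called in primitive and parietal endoderm and 0 of the 5 in basement membrane. Gata4 was then at 1.54 (adjusted p = 0.215), Sox7 at 1.25 (adjusted p = 0.237), Srgn at 1.87 (adjusted p = 0.19), Fbln1 at 1.15 (adjusted p = 0.0553) and Serpinh1 at 0.55 (adjusted p = 0.294).

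The lists of other cell types and of signalling held 0 to 5 called genes each. Of 21 neural genes 1 rose, Pax6 (1.26 ± 0.27), and 1 fell, Tubb3 (-1.14 ± 0.23), with 1 and 1 adjusted over the list alone. The neural list had camera adjusted p = 0.977, adjusted p = 0.991 with an estimated correlation. Of 20 mesoderm and primitive streak genes 3 rose, Twist1 (1.09 ± 0.19), Foxc1 (0.80 ± 0.12) and Foxc2, and 0 fell, with 3 and 0 adjusted over the list alone. The mesoderm list had camera adjusted p = 0.052, adjusted p = 0.535 with an estimated correlation. None of 14 trophoblast genes was called by limma, and 0 and 0 adjusted over the list alone. The trophoblast list had camera adjusted p = 0.988, adjusted p = 0.993 with an estimated correlation. Of 16 fibroblast genes 1 rose, the PDGF receptor gene Pdgfrb (1.21 ± 0.15), with 2 and 0 adjusted over the list alone. The fibroblast list had camera adjusted p = 0.331, adjusted p = 0.788 with an estimated correlation. In NODAL, BMP and TGF-beta signalling 4 of 16 genes rose, Lefty1 (2.52 ± 0.43), a NODAL inhibitor, Smad6 (1.19 ± 0.17), Tgfbr2 and Skil, and Bmp4 fell (-1.04 ± 0.19), with 7 and 2 adjusted over the list alone. The NODAL list had camera adjusted p = 0.015, adjusted p = 0.338 with an estimated correlation. In WNT signalling 0 of 19 genes rose and 2 fell, Notum (-1.20 ± 0.21) and Fzd5 (-0.65 ± 0.13), with 2 and 2 adjusted over the list alone. The WNT list had camera adjusted p = 0.605, adjusted p = 0.788 with an estimated correlation. Foxc1, Pdgfrb, Lefty1, Smad6 and Skil passed with the array set as a block. The others did not, among them Pax6 (adjusted p = 0.204), Tubb3 (adjusted p = 0.136), Twist1 (adjusted p = 0.0804), Bmp4 (adjusted p = 0.121) and Notum (adjusted p = 0.0702).

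The growth, metabolism and response lists held 0 to 3 called genes each. In DNA replication and S phase 0 of 23 genes rose and 1 fell, Uhrf1 (-0.91 ± 0.18), with 0 and 1 adjusted over the list alone. The DNA replication list had camera adjusted p = 5.17e-05, adjusted p = 0.409 with an estimated correlation. In mitosis 0 of 23 rose and Aurka fell (-0.55 ± 0.12), with 0 and 2 adjusted over the list alone. The mitosis list had camera adjusted p = 7.44e-05, adjusted p = 0.409 with an estimated correlation. Among CDK inhibitors and growth arrest genes 1 of 15 rose, Gadd45b (1.12 ± 0.18), with 4 and 0 adjusted over the list alone. The CDK inhibitor list had camera adjusted p = 0.00269, adjusted p = 0.279 with an estimated correlation. Among MYC, cyclin D and growth regulators 0 of 17 rose and 2 fell, Ccnd1 (-1.29 ± 0.23) and Cdk6 (-0.78 ± 0.20), with 0 and 5 adjusted over the list alone. The growth regulator list had camera adjusted p = 0.00422, adjusted p = 0.35 with an estimated correlation. Among p53 targets and apoptosis genes 1 of 17 rose, the survival factor Mcl1 (0.89 ± 0.17), with 1 and 0 adjusted over the list alone; camera's adjusted p lay just under the threshold, at 0.05 after rounding, and adjusted p = 0.279 with an estimated correlation. In hypoxia and glycolysis 1 of 19 genes rose, Vegfa (0.84 ± 0.18), and 1 fell, Pdk1 (-1.42 ± 0.20), with 1 and 4 adjusted over the list alone. The hypoxia list had camera adjusted p = 0.0362, adjusted p = 0.542 with an estimated correlation. In cholesterol synthesis limma called 0 of 18 genes, with 0 and 0 adjusted over the list alone and a median of -0.44 (camera adjusted p = 0.000193, adjusted p = 0.533 with an estimated correlation); the same median against vehicle replicate 1 alone was 0.03, and the list's median difference between vehicle replicates 1 and 2 was -1.11. For hypoxia and glycolysis the vehicle difference was -0.79. In the interferon response list 2 of 18 genes rose, B2m (1.88 ± 0.41) and Tap1 (0.68 ± 0.15), both of antigen presentation, and Ddx58 fell (-1.84 ± 0.41), with 2 and 1 adjusted over the list alone. The interferon list had camera adjusted p = 0.246, adjusted p = 0.497 with an estimated correlation. The stress and immediate early list (20 genes; camera adjusted p = 0.798, adjusted p = 0.831 with an estimated correlation) and the ribosomal protein list (18 genes; camera adjusted p = 0.53, adjusted p = 0.844 with an estimated correlation) had 0 genes called by limma, over all genes and adjusted over the list alone. Of the genes called in these lists Pdk1 passed with the array set as a block. Uhrf1 (adjusted p = 0.142), Aurka (adjusted p = 0.21), Gadd45b (adjusted p = 0.0744), Ccnd1 (adjusted p = 0.105), Cdk6, Mcl1, Vegfa, B2m (adjusted p = 0.227), Tap1 and Ddx58 did not.

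**Figure D2:**
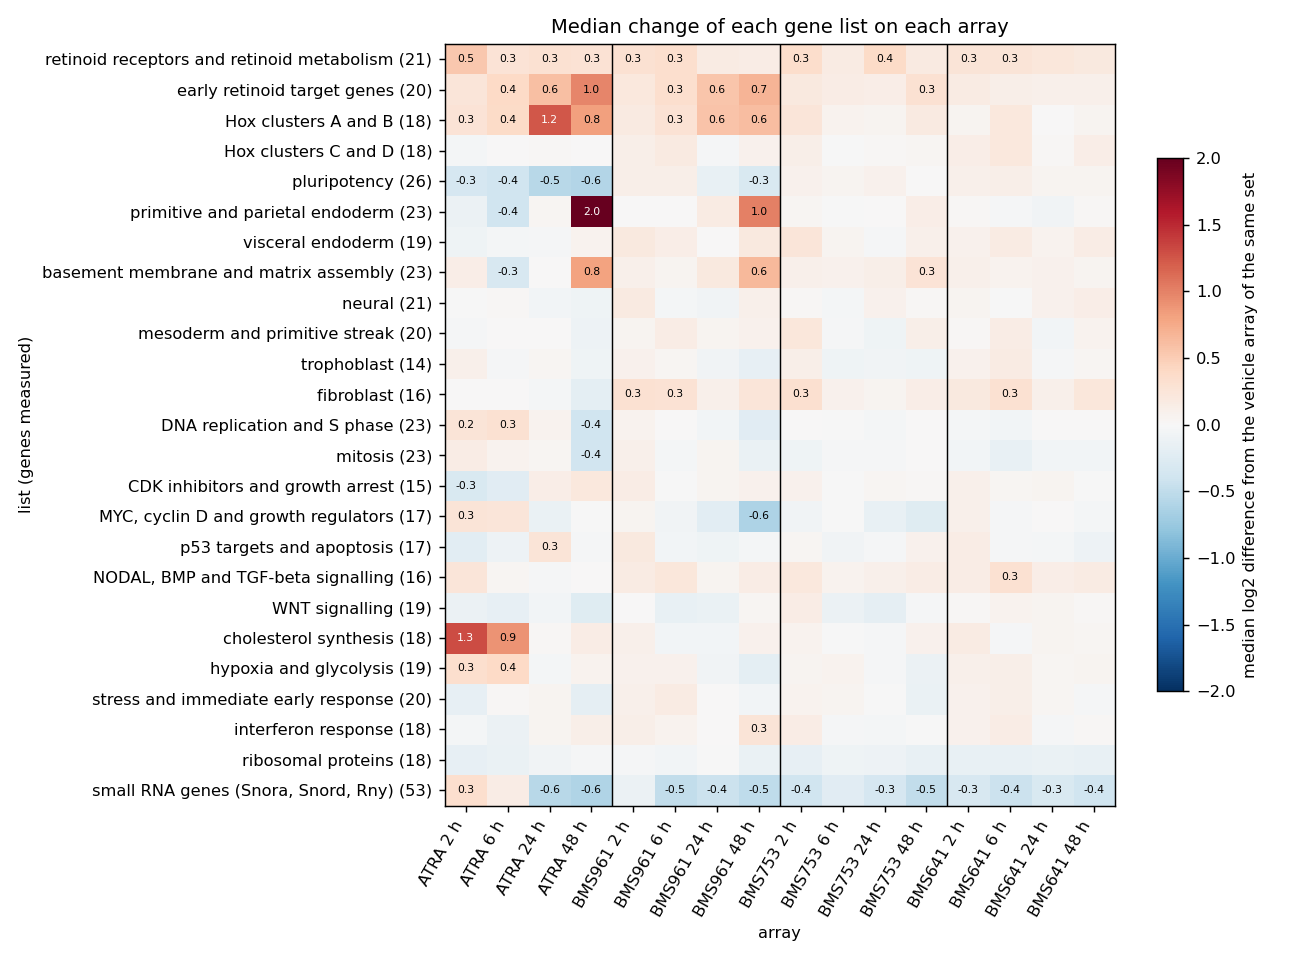
Median log2 difference of each gene list (vertical axis, genes measured in brackets) on each of the 16 retinoid arrays (horizontal axis) from the vehicle array of the same set, as colour from -2.0 to 2.0. The value is printed for all but the small differences. The sets were found in the data. Primitive and parietal endoderm stood at 2.02 with ATRA and 1.01 with BMS961 at 48 h, and cholesterol synthesis at 1.30 with ATRA at 2 h.

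Early ATRA arrays were compared with the 48 h vehicle, so they also differed from it in time in culture. Cyp26a1 rose by 5.22 ± 0.31 (37.4-fold, adjusted p = 3.78e-05), Hoxa5 by 2.73 ± 0.18, Rarb by 2.42 ± 0.35, the iron reductase gene Steap3 by 2.59 ± 0.24 and Aqp3 by 3.65 ± 0.77. Otx2 fell by 12.1-fold (-3.60 ± 0.38), followed by Dnmt3l (-2.58 ± 0.41), a partner of DNA methyltransferases, Mcf2, the cholesterol exporter Abca1 (-1.93 ± 0.15) and Fst (-1.90 ± 0.16). At 2 h alone the Cyp26a1 level was 10.06 with ATRA, 8.04 with BMS961, 6.56 with BMS753 and 4.94 with BMS641. Limma called 249 genes, 170 higher and 79 lower. With the array set as a block 455 genes were called and 9 of the 10 named genes passed, each except Aqp3 (2.18, adjusted p = 0.0862). The counts without vehicle replicate 1, vehicle replicate 2, the 2 h array and the 6 h array were 837, 455, 41 and 119.

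With BMS961, the RARγ agonist, Cyp26a1 rose late by 4.09 ± 0.31 (adjusted p = 0.000178), Gata6 by 3.62 ± 0.51 (12.3-fold), Rarb by 3.17 ± 0.35, Dhrs3 by 2.99 ± 0.42 and Hoxa5 by 2.91 ± 0.18. Other named rises were Fbp2 (3.52), an enzyme of gluconeogenesis, Cyp11a1 (2.75), which makes pregnenolone from cholesterol, Greb1l (2.67), the GDNF receptor gene Gfra1 (2.65) and Clgn (2.34). Otx2 fell by 9.04-fold (-3.18 ± 0.38, adjusted p = 0.00252) and the NODAL inhibitor Lefty2 by 8.72-fold (-3.13 ± 0.46). The other named falls were Trh (-2.94), Slc27a2 (-2.64), Platr8 (-2.50), Dnmt3l (-2.39), Enpp3 (-2.25), Fst (-2.22), Socs2 (-1.96) and Mcf2 (-1.89). Limma called 252 genes, 163 higher and 89 lower (156 and 131 after quantile normalization), and 142 changed at least 2-fold. All 20 named genes passed with the array set as a block, where 716 genes were called. The counts without vehicle replicate 1, vehicle replicate 2, the 24 h array and the 48 h array were 716, 815, 19 and 33.

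In the lists with late BMS961, retinoid metabolism had 4 rises and 0 falls (6 and 0 adjusted over the list alone; camera adjusted p = 0.00124, adjusted p = 0.134 with an estimated correlation). The early retinoid targets had 5 rises, with Foxa1 at 1.55 ± 0.28 and Nrip1 at 1.12 ± 0.17, and 1 fall (8 and 2 adjusted over the list alone). The early target list had camera adjusted p = 0.00529, adjusted p = 0.241 with an estimated correlation. In Hox clusters A and B Hoxa5 and Hoxb4 (1.27 ± 0.17) rose and 0 fell, with 8 and 0 adjusted over the list alone. The Hox A and B list had camera adjusted p = 8.77e-08, adjusted p = 0.244 with an estimated correlation. Of the pluripotency genes 0 rose and 4 fell (0 and 10 adjusted over the list alone). The falls were Dnmt3l, Tcl1 (-0.98 ± 0.17), Utf1 (-0.93 ± 0.11) and Gdf3 (-0.63 ± 0.12). The pluripotency list had camera adjusted p = 8.77e-08, adjusted p = 0.199 with an estimated correlation. In primitive and parietal endoderm Gata6 rose and Fst fell (2 and 1 adjusted over the list alone). The primitive endoderm list had camera adjusted p = 0.00402, adjusted p = 0.533 with an estimated correlation. The basement membrane list had 0 genes called by limma over all genes and 2 and 1 adjusted over the list alone. The basement membrane list had camera adjusted p = 0.0254, adjusted p = 0.652 with an estimated correlation. Cdk6 (-1.04 ± 0.20) fell among the growth regulators (1 and 1 adjusted over the list alone; camera adjusted p = 0.0272, adjusted p = 0.414 with an estimated correlation). Eda2r (-0.87 ± 0.14) fell among the p53 targets (1 and 4 adjusted over the list alone). The p53 target list had camera adjusted p = 0.0261, adjusted p = 0.241 with an estimated correlation. Cholesterol synthesis had 0 genes called and a median of 0.55 (camera adjusted p = 1.11e-06, adjusted p = 0.446 with an estimated correlation), against 0.03 when set against vehicle replicate 2 alone. Blocked by array set, 7 lists passed with BMS961. Pluripotency (adjusted p = 0.0586), p53 targets (adjusted p = 0.0842) and cholesterol synthesis (adjusted p = 0.859) no longer did, and DNA replication did (adjusted p = 0.0299). Of the list genes called with BMS961, Gdf3 alone did not pass with the block. Early, limma called 8 genes with BMS961. Cyp26a1 rose by 3.60 ± 0.31 (12.1-fold, adjusted p = 0.0022), Plk3 by 1.53 ± 0.21, Gadd45b by 1.38 ± 0.18, Sntb2 by 0.92 ± 0.13 and the lipase gene Lipe by 0.91 ± 0.13, and Fst fell (-1.45 ± 0.16). Of these 6 named genes Cyp26a1, Gadd45b and Fst passed with the array set as a block (11 genes called). The early count was 3 after quantile normalization (1 higher, 2 lower), 2 with centred arrays (1 higher, 1 lower), 1441 without vehicle replicate 2, 1 without the 2 h array and 0 without the 6 h array.

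BMS753, the RARα agonist, moved fewer genes past the threshold than ATRA or BMS961. With the array set as a block it no longer had fewer than ATRA. Late, Rarb rose by 2.31 ± 0.35 (4.96-fold, adjusted p = 0.0382), Cyp11a1 by 1.72 ± 0.22 and Greb1l by 1.63 ± 0.24. Fst fell by 3.94-fold (-1.98 ± 0.16, adjusted p = 0.000835), Otx2 by 4.87-fold (-2.28 ± 0.38) and the corepressor gene Bcor fell too (-0.91 ± 0.14). Further rises were Cdk15 (1.63), the cell polarity gene Llgl2 (1.58), Tmem45a (1.45), Ddc (1.43), which makes dopamine and serotonin, Plk3 (1.37), Sesn1 (1.31) and Sema3e (1.22). Cyp26a1 had a change of 0.91 ± 0.31 (adjusted p = 0.408) and Hoxa5 of 0.75 ± 0.18 (adjusted p = 0.18), which did not pass. Limma called 37 genes, 34 higher and 3 lower, 1 after quantile normalization (0 higher, 1 lower) and 21 with centred arrays. With the array set as a block 243 genes were called and 12 of the 13 named genes passed, all but Otx2 (adjusted p = 0.0558). The counts without vehicle replicate 1, vehicle replicate 2, the 24 h array and the 48 h array were 243, 739, 0 and 1.

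In the lists with late BMS753, retinoid metabolism had 1 rise, Rarb, and 0 falls (3 and 0 adjusted over the list alone; camera adjusted p = 0.00422, adjusted p = 0.192 with an estimated correlation). Pbx2 rose among the early targets (0.82 ± 0.14; 5 and 0 adjusted over the list alone; camera adjusted p = 0.112, adjusted p = 0.404 with an estimated correlation). Gadd45b rose among the CDK inhibitors and growth arrest genes (1.08 ± 0.18; 2 and 1 adjusted over the list alone), and Fst fell in primitive and parietal endoderm (0 and 1 adjusted over the list alone; camera adjusted p = 0.0376, adjusted p = 0.656 with an estimated correlation). The other lists that camera passed held 0 genes called by limma over all genes. Their medians were 0.60 for cholesterol synthesis (camera adjusted p = 1.98e-08, adjusted p = 0.394 with an estimated correlation) and 0.24 for hypoxia and glycolysis (camera adjusted p = 0.00787, adjusted p = 0.464 with an estimated correlation). Against vehicle replicate 2 alone these medians were 0.01 and -0.03, and with the array set as a block neither list passed (adjusted p = 0.943 and adjusted p = 0.704). Those of the next lists were 0.18 for DNA replication (camera adjusted p = 0.0194, adjusted p = 0.568 with an estimated correlation) and -0.17 for ribosomal proteins (camera adjusted p = 5.17e-05, adjusted p = 0.338 with an estimated correlation). They were -0.16 for pluripotency (camera adjusted p = 0.0218, adjusted p = 0.409 with an estimated correlation) and -0.11 for visceral endoderm (camera adjusted p = 0.0199, adjusted p = 0.409 with an estimated correlation). The last medians were -0.03 for mesoderm (camera adjusted p = 0.0416, adjusted p = 0.524 with an estimated correlation), -0.15 for trophoblast (camera adjusted p = 0.0169, adjusted p = 0.245 with an estimated correlation) and -0.10 for Hox clusters C and D (camera adjusted p = 0.0356, adjusted p = 0.409 with an estimated correlation). Blocked by array set, 4 lists passed, among them retinoid metabolism (adjusted p = 0.0222) and ribosomal proteins (adjusted p = 0.00645), and the list genes called with BMS753 (Rarb, Pbx2, Fst and Gadd45b) passed. Early, limma called 0 genes with BMS753 (1115 at an unadjusted p under 0.05) and 1288 without vehicle replicate 2.

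BMS641, the RARβ agonist, gave no called gene late. Cyp26a1 differed from vehicle by -0.12 ± 0.31, Hoxa5 by -0.36 ± 0.18, Rarb by -0.18 ± 0.35 and Gata6 by -0.25 ± 0.51. With the array set as a block these were -0.03, -0.34, 0.49 and 0.27, so the signs of Rarb and Gata6 turned, and none passed. Otx2 had a value of -1.16 ± 0.38 (adjusted p = 0.995) and Fst of -0.79 ± 0.16 (adjusted p = 0.995). Limma called 0 genes late (916 at an unadjusted p under 0.05) and 0 early (1501). With late BMS641 camera passed 9 lists, which held 0 genes called over all genes. The cholesterol list had a median of 0.63 (camera adjusted p = 1.61e-10, adjusted p = 0.35 with an estimated correlation) and hypoxia and glycolysis 0.46 (camera adjusted p = 0.00012, adjusted p = 0.35 with an estimated correlation). Set against vehicle replicate 2 alone they were 0.07 and 0.05, and blocked by array set neither passed (adjusted p = 0.991 and adjusted p = 0.785). Ribosomal proteins had a median of -0.18 (camera adjusted p = 3.88e-08, adjusted p = 0.241 with an estimated correlation) and primitive and parietal endoderm -0.23 (camera adjusted p = 0.00131, adjusted p = 0.504 with an estimated correlation). The medians of the other 5 were -0.11 for Hox clusters A and B (camera adjusted p = 0.0111, adjusted p = 0.464 with an estimated correlation) and 0.19 for DNA replication (camera adjusted p = 0.011, adjusted p = 0.545 with an estimated correlation). They were -0.17 for CDK inhibitors (camera adjusted p = 0.0313, adjusted p = 0.369 with an estimated correlation), 0.13 for growth regulators (camera adjusted p = 0.0289, adjusted p = 0.416 with an estimated correlation) and -0.10 for p53 targets (camera adjusted p = 0.0455, adjusted p = 0.279 with an estimated correlation). Blocked by array set, 2 lists passed, ribosomal proteins (adjusted p = 1.79e-05) and p53 targets (adjusted p = 0.0329). Without vehicle replicate 2 the counts of genes were 1024 late and 1466 early, and without vehicle replicate 1 they were 2 and 0.

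**Figure D3:**
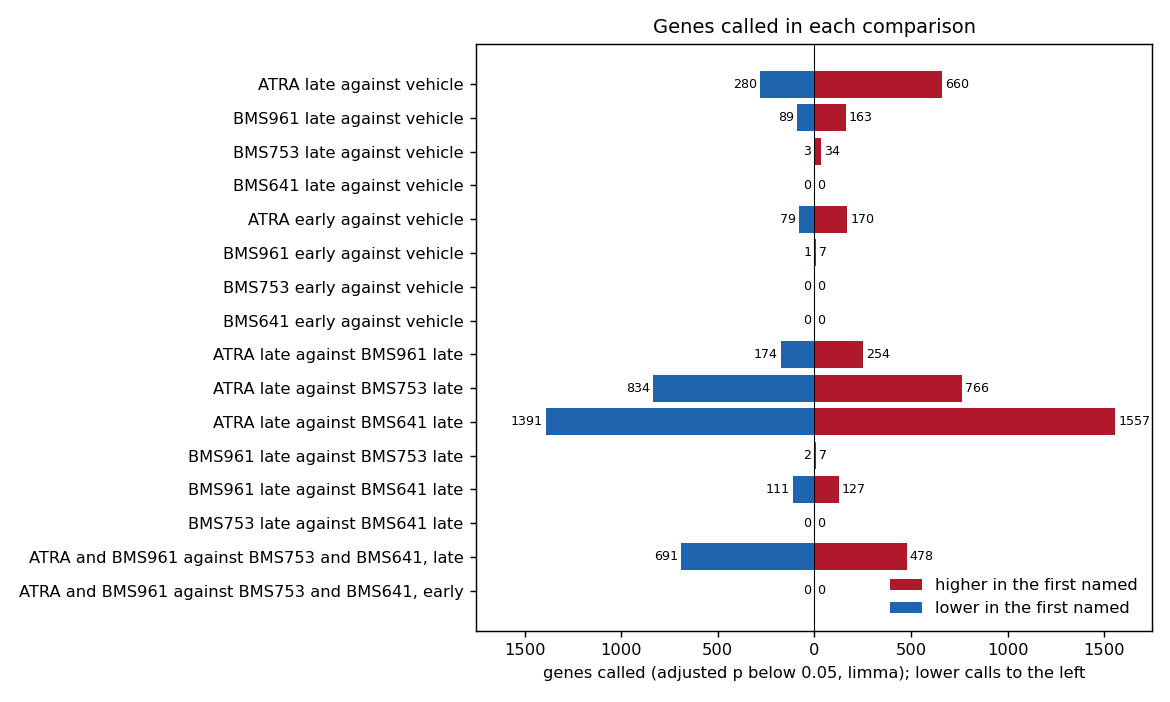
Genes called by limma at an adjusted p under 0.05 (horizontal axis, number of genes; higher to the right and lower to the left) in each comparison (vertical axis). ATRA late against vehicle had 660 higher and 280 lower calls, BMS961 163 and 89, BMS753 34 and 3, and BMS641 0 and 0.

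The 3 receptor-specific compounds were compared with each other at matched times, within the set of 13 arrays. BMS961 exceeded BMS753 late in Cyp26a1 by 3.18 ± 0.31 (9.04-fold, adjusted p = 0.00415) and in Hoxa5 by 2.16 ± 0.18 (4.47-fold, adjusted p = 0.00136), although its dose was 0.1 µM against 1 µM. Crygc, a lens crystallin gene (1.70 ± 0.19), Fbp1 (1.44 ± 0.19) and Slc26a10 (1.40 ± 0.20) were also higher with BMS961, and Enox1 (-1.28 ± 0.19) and the pluripotency factor gene Utf1 (-0.89 ± 0.11) lower. Limma called 9 genes (7 higher, 2 lower). For Stra8 the difference was 0.68 with a 95% interval of -1.17 to 2.53, for Aqp3 0.76 (-0.91 to 2.44), for Rarb 0.86 (0.09 to 1.62) and for Fst -0.24 (-0.59 to 0.10); none of these passed the test. The array set as a block cannot change a difference within 1 set, and alters only the spread. The 7 named genes passed with it (13 genes called), which is no test of the array set. The count was 5 after quantile normalization (5 higher, 0 lower), and 2, 1, 2 and 1 without the BMS961 arrays at 24 h and 48 h and the BMS753 arrays at 24 h and 48 h.

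BMS961 differed from BMS641 late in 238 genes, 127 higher and 111 lower. Calcoco2 was higher by 4.51 ± 0.83, Stra8 by 4.27 ± 0.85, Cyp26a1 by 4.21 ± 0.31 (18.6-fold, adjusted p = 0.000202), Aqp3 by 4.01 ± 0.77 and Gata6 by 3.87 ± 0.51. Slc27a2 (-2.83), an acyl-CoA synthetase of very long fatty acids, Platr8 (-2.71), Dnmt3l (-2.53), Lefty2 (-2.39) and the hormone precursor gene Trh (-2.37) were lower. These 10 genes passed with the array set as a block, where 641 genes were called, as without either vehicle array. The block changed the spread and not these differences, so it is no test of the array set here. The counts without the BMS961 arrays at 24 h and 48 h and the BMS641 arrays at 24 h and 48 h were 25, 26, 67 and 20. Between BMS753 and BMS641, both at 1 µM, limma called 0 genes late (810 at an unadjusted p under 0.05). Among genes chosen after their values were seen, Stra8 was at 3.59 (95% interval 1.74 to 5.44), Aqp3 at 3.25 (1.58 to 4.92), Rarb at 2.49 (1.72 to 3.25) and Otx2 at -1.12 (-1.95 to -0.30), unadjusted for the number of genes. For Gata4 the difference was 0.19 (-0.76 to 1.15), and the median half-width of the interval over all genes was 0.35. The array set as a block, like leaving out either vehicle array, gave 38 calls between BMS753 and BMS641.

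ATRA was also compared with each BMS compound at matched late times, across the array sets. Against BMS753, ATRA was higher in Cyp26a1 by 5.63 ± 0.31 (49.3-fold; 5.43 with the array set as a block, adjusted p = 0.0059) and in Hoxa5 by 3.81 ± 0.18 (3.76 with the block, adjusted p = 0.00257). Against BMS641 the difference was 6.66 ± 0.31 for Cyp26a1 (6.46 with the block, adjusted p = 0.00153) and 4.92 ± 0.18 for Hoxa5 (4.88, adjusted p = 0.000175). These were the named genes of the ATRA pairs that passed with the block. Gpr50 (3.79), Srgn (3.67) and Dab2 (3.62) were higher and Septin1 (-2.59), the WNT inhibitor Notum (-2.32), Tcea3 (-2.24), Myc (-2.13) and Akr1b8 (-2.08) lower than with BMS753. With the block Dab2 was at 0.93, Myc at -0.69 and Akr1b8 at -0.06. Calcoco2 (4.61), Srgn (4.58) and Stra8 (4.57) were higher and Krt17 (-3.03), Pcolce2 (-2.87), Myc (-2.75), Platr8 (-2.59) and Ntn1 (-2.55) lower than with BMS641. With the block Stra8 was at 1.31 and the keratin gene Krt17 at 0.02, where its sign turned. The calls were 1600 against BMS753 (766 higher, 834 lower) and 2948 against BMS641 (1557 and 1391), and with centred arrays 511 and 1440, and 1089 and 2479. They were 11 and 13 with the array set as a block.

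Against BMS961, ATRA was higher late in Lefty2 by 4.31 ± 0.46 (2.79 with the array set as a block), Meioc by 3.29 ± 0.47, Lefty1 by 3.07 ± 0.43, B4galnt2 by 2.86 ± 0.65 and Cyp26a1 by 2.45 ± 0.31 (2.25 with the block, adjusted p = 0.266). It was lower in Snora16a (-2.21), Mep1b (-2.06), Akr1b8 (-1.95), Rny3 (-1.90) and Septin1 (-1.87). With the block Meioc was at 1.37, Lefty1 at 1.22, Snora16a at -0.23, Mep1b at -1.21, Rny3 at -1.14 and Septin1 at -1.92. Limma called 428 genes, 254 higher and 174 lower, and 8 with the block, where 0 of the 10 named genes passed and the signs of B4galnt2 (-0.14) and Akr1b8 (0.07) turned. Of the 23 primitive and parietal endoderm genes 1 was called, Clic6 (1.43 ± 0.18, adjusted p = 0.00797; adjusted p = 0.359 with the block). Gata6 was at -0.26 (95% interval -1.37 to 0.85), Gata4 at 0.67 (-0.28 to 1.63), Srgn at 1.82 (interval from 0.30 upward), Krt18 at 1.80 (0.74 to 2.86) and Fst at 0.54 (0.20 to 0.88), intervals unadjusted for the number of genes. Without either vehicle array the counts against BMS961 were 1969 and against BMS753 3230. Without the ATRA array at 24 h and at 48 h they were 928 and 40 against BMS961, and without the BMS961 arrays 5 and 0. Those counts were, without the ATRA array at 48 h 202 against BMS753 and 895 against BMS641, without the BMS753 arrays at 24 h and 48 h 56 and 17, and without the BMS641 arrays 969 and 67.

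Genes called late against vehicle were shared between retinoids in the same direction. ATRA and BMS961 shared 154 genes, 99 higher and 55 lower, against 5.4 and 1.25 for independent lists. ATRA and BMS753 shared 25 (23 higher and 2 lower, against 1.13 and 0.0421), and BMS961 and BMS753 shared 33 (30 and 3, against 0.278 and 0.0134). Across genes, which are not independent replicates, the correlation of the changes was 0.546 for ATRA and BMS961 (0.499 in unchanged groups simulated against shared vehicle arrays; covariance 0.0687 against 0.0177), 0.244 for ATRA and BMS753 (0.5; 0.0246 against 0.0177) and 0.742 for BMS961 and BMS753 (0.5; 0.0577 against 0.0177). With BMS641 the correlation was -0.224 for ATRA, 0.319 for BMS961 and 0.599 for BMS753 (covariance -0.018, 0.0198 and 0.0297), and 0 calls were shared. Part of the excess may come from the shared controls. The vehicle arrays lay further apart (SD over genes of their log2 difference 0.44) than a covariance of 0.0177 implies. The simulations may therefore set the effect of shared controls too low. With the array set as a block, which gives ATRA a separate vehicle array, ATRA shared 102 calls with BMS961 and 47 with BMS753. The 223 calls shared by BMS961 and BMS753 still had vehicle replicate 2 in common.

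The next comparison asks what the retinoids that act on RARγ, ATRA and BMS961, had in common against BMS753 and BMS641. The fit counted the 24 h and 48 h arrays of a retinoid as separate observations, though they are not independent. Its p-values may therefore be too small. Late, Cyp26a1 was higher by 4.92 ± 0.71 (30.3-fold, adjusted p = 0.00548), Hoxa5 by 3.54 ± 0.64, Gata6 by 3.03 ± 0.46, Srgn by 3.21 ± 0.49, and Dab2 and Pdgfra, both markers of primitive endoderm, by 2.91 ± 0.65 and 2.87 ± 0.44. Higher too were Calcoco2 (3.07), the desmosomal cadherin gene Dsc2 (2.57), Fbp2 (2.51) and Hoxb2 (2.47). Lower were Platr8 (-2.10), Krt17 (-2.05), Pcolce2 (-2.02), Enox1 (-1.87), Ntn1 (-1.80), Pdzd4 (-1.76), Slc27a2 (-1.75), Nkx6-3 (-1.65), Septin1 (-1.62) and Sulf1 (-1.62), which edits heparan sulfate. Limma called 1169 genes, 478 higher and 691 lower. The array medians over the 19938 genes lay 0.11 higher with ATRA and BMS961, the median difference over genes was -0.01, and with centred arrays 361 genes were higher and 1664 lower. Without ATRA 550 genes were called (210 higher, 340 lower), without BMS961 4575, without BMS753 138 and without BMS641 0. Of the 20 named genes 17 passed without ATRA, and Calcoco2 (3.02, adjusted p = 0.0816), Dab2 (2.10, adjusted p = 0.0749) and Sulf1 (-1.16, adjusted p = 0.0517) did not. Without ATRA the fit set BMS961 alone against BMS753 and BMS641. It used the BMS961 arrays on which the genes were named, so it is no separate check of what ATRA and BMS961 share. Leaving out single arrays gave 81 (BMS641 at 48 h) to 2519 (BMS961 at 24 h), with 209 without BMS641 at 24 h, 382 and 506 without ATRA at 48 h and 24 h, 656 without BMS753 at 48 h and 2166 without BMS961 at 48 h.

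In this late class comparison 12 of 23 primitive and parietal endoderm genes were higher and 0 lower (19 and 0 adjusted over the list alone), among them Gata4 (1.94 ± 0.30), Cubn (2.29 ± 0.55), an endocytic receptor, and Plat (2.04 ± 0.52), the tissue plasminogen activator. The primitive endoderm list had camera adjusted p = 1.16e-12, adjusted p = 0.235 with an estimated correlation. In basement membrane and matrix assembly 6 were higher and 0 lower (11 and 0 adjusted over the list alone), with Lamb1 (1.37 ± 0.38), Col4a2 (1.21 ± 0.33) and Col4a1 (1.06 ± 0.28), chains of laminin and type IV collagen. The basement membrane list had camera adjusted p = 4.6e-07, adjusted p = 0.369 with an estimated correlation. In Hox clusters A and B 9 were higher and 0 lower (15 and 0 adjusted over the list alone; camera adjusted p = 2.05e-11, adjusted p = 0.241 with an estimated correlation). In retinoid metabolism 5 were higher and 0 lower (8 and 1 adjusted over the list alone). The retinoid metabolism list had camera adjusted p = 0.0261, adjusted p = 0.35 with an estimated correlation. Of the early targets 7 were higher and 2 lower, Gbx2 (-1.03 ± 0.19) and Pdgfa (11 and 2 adjusted over the list alone). The early target list had camera adjusted p = 0.000702, adjusted p = 0.241 with an estimated correlation. Of the pluripotency genes 1 was higher and 10 lower (2 and 14 adjusted over the list alone). Klf4 was higher (1.01 ± 0.27), and among the lower were Utf1 at -0.98 ± 0.09, Tdgf1 at -0.99 ± 0.17 and Lin28a at -0.81 ± 0.20. The pluripotency list had camera adjusted p = 0.000702, adjusted p = 0.0941 with an estimated correlation. Lower too were 4 DNA replication genes, with Ccne1 at -0.78 ± 0.14 (0 and 9 adjusted over the list alone; camera adjusted p = 1.11e-06, adjusted p = 0.35 with an estimated correlation), as were 4 growth regulators, with Myc at -1.61 ± 0.41 and Ccnd1 at -1.22 ± 0.32 (0 and 4 adjusted over the list alone; camera adjusted p = 0.00082, adjusted p = 0.224 with an estimated correlation). In hypoxia and glycolysis 1 was higher and 6 lower (3 and 12 adjusted over the list alone). Among the lower were Ndrg1 at -1.39 ± 0.37 and Pdk1 at -1.29 ± 0.20. The hypoxia list had camera adjusted p = 0.00123, adjusted p = 0.35 with an estimated correlation. Idi1 (-1.21 ± 0.31) was lower in cholesterol synthesis (0 and 11 adjusted over the list alone; camera adjusted p = 1.78e-06, adjusted p = 0.43 with an estimated correlation). Dkk1 (1.64 ± 0.39) was higher in visceral endoderm (1 and 0 adjusted over the list alone; camera adjusted p = 0.00891, adjusted p = 0.369 with an estimated correlation), and Eomes and Foxc1 higher in mesoderm (5 and 0 adjusted over the list alone). The mesoderm list had camera adjusted p = 0.00428, adjusted p = 0.369 with an estimated correlation.

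The remaining lists past the preset threshold in the class comparison were mitosis (camera adjusted p = 0.0137, adjusted p = 0.545 with an estimated correlation), CDK inhibitors (camera adjusted p = 0.00428, adjusted p = 0.338 with an estimated correlation), Hox clusters C and D (camera adjusted p = 0.0331, adjusted p = 0.521 with an estimated correlation) and ribosomal proteins (camera adjusted p = 0.00402, adjusted p = 0.35 with an estimated correlation), with 0 genes called by limma except Rps19 (0.52 ± 0.11). Without ATRA, so with BMS961 alone against BMS753 and BMS641, camera passed 9 lists instead of 16. Among them were primitive and parietal endoderm (adjusted p = 1.26e-11), Hox clusters A and B (adjusted p = 2.94e-12), pluripotency (adjusted p = 5.16e-05) and growth regulators (adjusted p = 0.000184). Cholesterol synthesis then had an adjusted p of 0.464. By single genes, 6 of the 12 called in primitive and parietal endoderm passed without ATRA, 2 of 6 in basement membrane, 6 of 9 in Hox clusters A and B, 3 of 5 in retinoid metabolism, 6 of 9 early targets and 10 of 11 in pluripotency. The counts were 2 of 4 in DNA replication, 0 of 4 growth regulators and 2 of 7 in hypoxia and glycolysis. Early, limma called 0 genes between the classes (1732 at an unadjusted p under 0.05), and the test of late minus early also called 0 (1638). Cyp26a1 was at 3.53 ± 0.71 early and Hoxa5 at 1.64 ± 0.64, with adjusted p of 0.482 and 0.515. Without BMS961 the early count was 928 and the count of the difference 830, and without its 24 h array 18 genes differed late minus early.

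At single times the number of genes at least 2-fold from both vehicle arrays, a count with no test, was highest at 48 h for ATRA, BMS961 and BMS753. For ATRA 91 genes were higher and 52 lower at 2 h, 81 and 39 at 6 h, 106 and 60 at 24 h, and 650 and 116 at 48 h. For BMS961 the counts were 5 and 2, 16 and 13, 93 and 25, and 202 and 70, and for BMS753 1 and 4, 4 and 1, 19 and 5, and 50 and 15. BMS641 had 0 and 0, 0 and 3, 1 and 0, and 1 and 1. Lama1, a laminin chain of basement membrane, stood at 10.40 with ATRA and 9.70 with BMS961 at 48 h, at 7.24 and 6.80 with BMS753 and BMS641, and at 7.04 and 6.96 in vehicle. Against the vehicle array of the same set, 48 h gave 807 and 212 genes for ATRA, 498 and 299 for BMS961, 267 and 151 for BMS753 and 39 and 25 for BMS641.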

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

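The tests of the array set, the state of vehicle replicate 1, culture time, gene choice and a common fraction were chosen after the results were seen; the counts over other splits of the arrays were planned.

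The effects of retinoids against vehicle differed from each other in limma's direct tests late: 428 genes between ATRA and BMS961, 1600 between ATRA and BMS753, 2948 between ATRA and BMS641, 9 between BMS961 and BMS753 and 238 between BMS961 and BMS641. The counts that involve ATRA were 8, 11 and 13 with the array set as a block. The probe sets without a listed gene, which no comparison of genes used, held 5 called in ATRA late against vehicle (1 higher, 4 lower), 25 in ATRA against BMS753 (1 and 24) and 42 in ATRA against BMS641 (9 and 33). Probe set 10544746 rose by 4.35 ± 0.49 (20.4-fold, adjusted p = 0.0198; 3.44 with the array set as a block, adjusted p = 0.0134), and 10474520 and 10420780 changed by -3.19 ± 0.23 and -2.53 ± 0.19 (adjusted p = 0.000955 each; 0.0134 with the block). The other 2 of the 5 did not pass with the block (adjusted p = 0.0707 and adjusted p = 0.403). The first 3 were singled out after their values were seen.

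The vehicle arrays were at least 2-fold apart in 665 genes. Over these genes the ATRA array at 6 h departed from the BMS arrays at 6 h toward vehicle replicate 1 in 94.4%, and in 94.6% of the 257 among them that BMS961 and BMS641 left within 0.3 of each other, so an array set shared by vehicle replicate 1 and the ATRA arrays is a candidate explanation. A retinoid-like state of the cells of vehicle replicate 1 may also account for part: the 41 genes moved one way, by at least 0.3, in all 8 BMS961 and BMS753 arrays against BMS641 at the same time were shifted by a median of 0.794 in vehicle replicate 1 against 2 (90.2% the same way), more than the 0.483 of the least moved of those arrays. Among genes with a symbol that ATRA moved late, Cyp26a1 (the largest called rise) and Otx2 (the largest called fall) differed by 0.20 and 0.17 between the vehicle arrays. These genes do not stand for the others. Against vehicle replicate 1 alone Stra8, Calcoco2 and Aqp3 changed by 2.16, 1.74 and 1.91, against 3.80, 3.50 and 3.37 with both vehicle arrays. Of the named rises with late ATRA only Crabp2 changed more against vehicle replicate 1 alone (3.86 against 3.66). Both explanations remain open, and whether the sets were cultured or hybridised apart is not given in the sources used here.

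ATRA at 2 h differed 2-fold from vehicle replicate 1 in 457 genes, more than at 6 h (291) or 24 h (192). Vehicle replicate 2 departed from vehicle replicate 1 the same way in 76.6% of these genes, by a median of 0.743 against 1.25 for ATRA at 2 h. The genes were chosen on their difference from vehicle replicate 1, whose own spread turns both departures the same way. This share therefore cannot decide, and a departure of vehicle replicate 1 remains a candidate explanation. The shorter time in culture cannot be told apart from the effect of ATRA: the BMS641 array at 2 h differed 2-fold from vehicle replicate 2 in 5 genes, but the departure of the ATRA arrays declined from 1.25 at 2 h to 0.899 at 6 h and 0.122 at 24 h, and no vehicle was taken at 2 h. A biological effect of early ATRA stays open.

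Measured from BMS641, BMS753 moved the genes of the BMS961 response by less than BMS961 did. This held in 236 of the 238 genes called between BMS961 and BMS641, with a median ratio of 0.5. The shifts and ratios in this paragraph are differences from BMS641 and not from vehicle. They are therefore not fractions of the change from vehicle. Choice of the genes on the BMS961 arrays was argued against: of 175 genes called on the ATRA arrays with the array set as a block, BMS961 moved 92% of them further than BMS753 did from BMS641 in the ATRA direction, with median shifts of 0.767 and 0.338. One common fraction of the BMS961 response at every gene (0.495) stays open: limma found 0 of the 175 genes departing from it after adjustment, which does not show that they share it, and 17 at an unadjusted p under 0.05, against 8.75 by chance. Ratios of single genes, such as 0.246 for Cyp26a1, 0.34 for Hoxa5, 0.744 for Rarb and 0.84 for Stra8, leave open that BMS961 and BMS753 differ in kind for some genes, and the dose of BMS961 was 0.1 µM against 1 µM. The preference for RARγ or RARα stays among the open explanations, untested.

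For the late comparison of ATRA and BMS961 with BMS753 and BMS641, 1 of the 34 splits of the 8 late arrays into 4 and 4 that could be fitted, the real one, gave as many as the 1169 calls, and the highest other gave 2. Most of these splits divided the arrays of a retinoid between the groups, which puts differences between retinoids into the spread. They therefore cannot exclude chance. The 24 h and 48 h arrays of a retinoid are not independent: 3 splits kept each retinoid whole, the real one with 1169 calls and the other 2 with 0, too few for a share under 0.05. Without BMS641 the count was 0. Early the real split gave 0 calls, as did the highest other, so 34 of 34 gave as many. A real count of 0 fixes that outcome, so it says nothing about chance, which was not excluded. For the difference of late minus early 100 of 100 drawn pairs of splits gave at least the real count of 0, an outcome which that count also fixes. The highest other gave 1076, and what set that pair of splits apart was not tested.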

How the results depend on the processing

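The array set as a block, the same-set vehicle and the lists without ATRA or without single vehicle arrays were chosen after seeing the data; the other alternatives were planned. For named genes 1363 values kept direction and side of the threshold, 519 kept the direction but no longer passed and 3 turned. All 3 turned with the array set as a block: B4galnt2 (-0.135) and Akr1b8 (0.071) between ATRA and BMS961, and Krt17 (0.018) between ATRA and BMS641. Genes were named only if the arrays compared moved one way, so few settings could turn a sign. The counts of kept directions therefore do not show that directions are stable. Of the values of lists 290 kept both, 139 no longer passed and 16 turned. Counts of genes called stayed within 1.5 times the reported count in 148 settings and moved in 115. The 148 include comparisons that had no calls and still had none. The cause was not tested unless stated. Signal over background is not given in the sources used here, so no gene was judged undetected. No analysis paired by replicate number was possible because the groups compared share fewer than 2 replicate numbers. Retinoids were compared with each other at matched times, and the class comparison was matched by time.

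A minimum of 2-fold, which can only remove calls, left 421 genes in ATRA late, 142 in BMS961 late, 24 in BMS753 late, 135 in ATRA early and 4 in BMS961 early against vehicle. It left 163, 495 and 927 between ATRA and BMS961, BMS753 and BMS641, 145 between BMS961 and BMS641, 215 in the late class comparison and 86 calls shared by ATRA and BMS961. With late arrays and vehicle only, so fewer samples, the counts were 85, 35 and 0 for ATRA, BMS961 and BMS753 late, 0, 72 and 891 for ATRA against BMS961, BMS753 and BMS641, 0 for BMS961 against BMS753 and 23 against BMS641. With 17 group means and 1 residual degree of freedom they were 2 for ATRA late and 0 for BMS961 late, BMS753 late, ATRA early and BMS961 early.

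With the array set as a block the counts were 175, 716, 243 and 2 for ATRA, BMS961, BMS753 and BMS641 late and 455 for ATRA early. They were 8, 11 and 13 for ATRA against BMS961, BMS753 and BMS641, 641 for BMS961 against BMS641 and 38 for BMS753 against BMS641. Shared calls were 102 (ATRA and BMS961), 47 (ATRA and BMS753), 223 (BMS961 and BMS753) and 2 for each pair with BMS641. The lists past the threshold were 10, 7, 4 and 2 for ATRA, BMS961, BMS753 and BMS641, and 9 in the class comparison without ATRA.

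Quantile normalization gave 1 gene in BMS753 late, 3 in BMS961 early, 5 between BMS961 and BMS753, 4 past 2-fold with BMS641 at 48 h and 6 lists in BMS753. Arrays centred on their median gave 21 genes in BMS753 late, 2 in BMS961 early, 234 between ATRA and BMS961, 2025 in the late class comparison and 6 past 2-fold with BMS641 at 48 h. No common steps gave 5 in BMS961 early, 1 in BMS753 early, 697 between ATRA and BMS961, 4 between BMS961 and BMS753 and 1 between BMS753 and BMS641. Genes above the median mean level only, so fewer genes, gave 3 between BMS961 and BMS753, 494 past 2-fold with ATRA at 48 h and 5 lists in BMS641. The mean of a gene's probe sets gave 2 and eBayes with trend and robust 1 between BMS753 and BMS641. A fit with each ligand within phase plus time, whose spread leaves out differences between ligands of a class, gave 3245 late, 322 early and 233 for the difference between classes. With the estimated correlation 0 lists passed for ATRA, BMS961, BMS753, BMS641 or the classes.

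At 48 h a threshold of 1.5-fold gave 1858, 854, 308 and 37 genes for ATRA, BMS961, BMS753 and BMS641, and 3-fold 283, 90, 10 and 0. Against the mean of the vehicle arrays the counts were 1204, 509, 191 and 27, and against the vehicle array of the same set 797, 418 and 64 for BMS961, BMS753 and BMS641.

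Leaving out 1 array at a time gave 148 to 3594 genes for ATRA late, 19 to 815 for BMS961 late, 0 to 739 for BMS753 late and 0 to 1024 for BMS641 late. Early the ranges were 41 to 837 for ATRA, 0 to 1441 for BMS961, 0 to 1288 for BMS753 and 0 to 1466 for BMS641. Between retinoids they were 0 to 1969 (ATRA and BMS961), 17 to 3230 (ATRA and BMS753), 67 to 4188 (ATRA and BMS641), 1 to 13 (BMS961 and BMS753), 20 to 641 (BMS961 and BMS641) and 0 to 38 (BMS753 and BMS641). In the class comparisons, where whole retinoids were left out too, they were 0 to 4575 late, 0 to 928 early and 0 to 830 for the difference. For lists they were 10 to 15 in ATRA, 4 to 10 in BMS753 and 2 to 11 in BMS641 late. A lone remaining array was assumed to vary like the other groups.

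The 8 lists that turned are given with their adjusted p with the array set as a block, and then the range without either vehicle array, whose larger end was the one that turned. In ATRA late they were 0.5 and 5.26e-13 to 0.369 for cholesterol synthesis, and 0.657 and 5.16e-05 to 0.532 for hypoxia and glycolysis. In BMS961 late cholesterol synthesis had 0.859 and 1.92e-22 to 0.844. In BMS753 late pluripotency had 0.657 and 0.000112 to 0.626, DNA replication 0.704 and 8.03e-05 to 0.695, and hypoxia and glycolysis 0.704 and 2.39e-07 to 0.695. In BMS641 late DNA replication had 0.627 and 0.000112 to 0.588, and growth regulators 0.704 and 0.00344 to 0.688. None of them passed the threshold in the other direction.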

Other observations

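The genes and values in this part were chosen after seeing the data, and no test was planned for them beyond the fits above.

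Further Hox genes, not named above, rose with late ATRA against vehicle in limma's fit: Hoxb9 by 1.87 ± 0.19 (adjusted p = 0.00065), Hoxa3 by 1.53 ± 0.16, Hoxb6 by 1.53 ± 0.16, Hoxa2 by 1.51 ± 0.16 and Hoxb1 by 1.60 ± 0.26 (adjusted p = 0.00746). With the array set as a block Hoxb9 (1.57, adjusted p = 0.00244), Hoxa3 (1.28), Hoxb6 (1.43) and Hoxa2 (1.46) passed, and Hoxb1 did not (1.29, adjusted p = 0.0653). With late BMS961 limma called none of the 5, with Hoxb9 at 0.36 ± 0.19 and Hoxa2 at 0.67 ± 0.16, and with the block Hoxa3 passed (0.80, adjusted p = 0.0102). Hoxa2 stood at 4.96, 5.28, 5.73 and 6.27 at 2, 6, 24 and 48 h of ATRA, against 4.54 and 4.43 in vehicle. Meis1, a partner of Hox proteins, rose by 2.36 ± 0.52 (adjusted p = 0.0283; 0.134 with the block), and stood at 8.91 with ATRA, 7.51 with BMS961, 6.26 with BMS753 and 5.08 with BMS641 at 48 h.

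Among genes of pluripotent cells, Nr5a2, a nuclear receptor, fell with late ATRA (-1.71 ± 0.27, adjusted p = 0.00661; -1.24 with the block, adjusted p = 0.0342), as did the growth factor gene Fgf4 (-1.05 ± 0.23; -1.37 with the block, adjusted p = 0.0267). Klf4 and Tbx3 stood apart between the vehicle arrays, at 10.46 and 7.20 for Klf4 and 10.75 and 7.27 for Tbx3. With BMS961 Tbx3 stood at 8.50, 8.96, 10.19 and 10.87 over time, with BMS753 at 8.22 at 2 h and 10.45 at 48 h, and with BMS641 at 7.97 and 9.03.

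Cholesterol synthesis genes differed with time among the ATRA arrays. Idi1 stood at 10.71, 10.16, 8.41 and 8.67 at 2, 6, 24 and 48 h, and at 8.68 and 10.65 in vehicle replicates 1 and 2. The list median against the vehicle array of the same set was 1.30, 0.89, 0.03 and 0.16 for ATRA at these times and lay between -0.06 and 0.16 on the 12 BMS arrays. The 53 small RNA genes (Snora, Snord and Rny) deviated from their means by a median of -0.41 in vehicle replicate 1 and 0.58 in replicate 2. With ATRA the deviation was -0.03, -0.08, -0.91 and -0.96 at 2, 6, 24 and 48 h, and on the BMS arrays it lay between -0.01 and 0.39.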
